A study of Mus musculus with 10 samples.

How the data were processed

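RNA sequencing counts were analysed from 10 libraries in 4 groups. MLTC-1, a mouse Leydig cell tumour line, was given DMSO, the solvent control (n = 3), or hymeglusin (n = 3), a beta-lactone that inhibits the cytosolic HMG-CoA synthase. Primary Leydig cells, the testosterone-producing cells between the seminiferous tubules, came from the testes of mice aged 2 months (n = 2) and 24 months (n = 2). Groups and replicate numbers were taken from the labels, which give neither the dose and duration of hymeglusin nor how the primary cells were isolated. RNA was extracted with an RNeasy kit, and 1.3 µg of total RNA went into NEBNext Ultra RNA libraries, per the labels' protocols.

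The deposited values are raw counts per gene symbol, whole numbers that the authors had not normalized. The tools named are fastp 0.23.4, FastQC 0.12.1, HISAT2 2.2.1 and featureCounts 2.0.6, with the mm10 build, per the submitters' processing notes. Their options, including the strand setting and the gene annotation of the counting, are not given in the sources used here. Reads of overlapping genes cannot then be told apart, which concerns Insl3, which lies within the bounds of Jak3. Reads of near-identical copies may have been split or dropped, which leaves the levels of Obp2a, Obp2b, Cyp21a1, Kng2 and Gsta2 uncertain. The table held 25239 symbols with 0 duplicates, and 0 columns of values belonged to no sample. It held 0 members of a list for the mitochondrial genome, which was not analysed here.

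Total counts per library ranged from 17407456 to 34787330. A gene with 0 counts in a library may be present at up to 3 counts, or 0.0862 to 0.172 CPM, the count scaled to library size. Folds against a group at 0 were computed against 3 counts over the whole group and are given as lower bounds, and ratios with 1 to 3 counts in the lower group carry a 95% exact Poisson interval. Floors and intervals cover counting error only, since reads without molecular identifiers are not independent molecules. Counts of replicate pairs were compared by chi-square over genes with at least 10 counts in the pair. The statistic per degree of freedom was 3.44 to 7.67 in the MLTC-1 groups, 18.9 at 2 months and 134 at 24 months, so each library was counted as a sample of its own.

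Counts were analysed with edgeR 4.0.16 in R 4.3.3. The 6 MLTC-1 libraries and the 4 primary cell libraries were fitted separately. Genes were kept by filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM, and groups were compared by the robust quasi-likelihood F-test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Adjusted p-values of genes come from this test unless another is named. The standard error (SE) of a log2 fold change is its size divided by the square root of F. Group levels are means ± SD of TMM-scaled CPM. Summed levels of a list were instead scaled by TMM over all libraries of both cell types without the count filter. They are therefore not on the scale of the CPM of single genes.

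Of 34 gene lists, those with at least 3 tested members were tested with camera (limma 3.58.1, preset inter-gene correlation 0.01, two-sided, Benjamini-Hochberg over the lists), a competitive test that sets a list against all other tested genes. The test was repeated with the correlation estimated from the data. An alternative, fry, tests whether a list's members move on balance in 1 direction and compares them with no other genes. Overlaps of the calls were tested by Fisher's exact test, two-sided, and the 200 genes of smallest p in each direction of a comparison were tested by camera in the other.

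Genes were named by a rule. Per comparison, it took the 10 genes with the largest fold in each direction among those past the threshold with a mean log2 CPM of at least 2 and no overlap between the groups, leaving out clone names and pseudogenes. It also took every tested member of the list for ketone body synthesis and use, 11 fixed genes of steroid synthesis, Leydig cell function and ageing, and up to 2 members of each other list per direction by adjusted p. For the overlap it took 10 genes called in the same direction and 5 in opposite directions. Not every gene taken by the rule is reported here. The groups, tests, lists, this rule and all alternative settings except the offsets were chosen before the data were examined.

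The alternative settings were RLE, upper quartile and total-count scaling, DESeq2 1.42.0, limma-voom, no count filter, a filter at 10 CPM, a minimum log2 fold change of 1, the replicate number as a block, 1 fit of all 10 libraries, and leaving out each library. Offsets for smooth trends on transcript length, and on length and GC content, were chosen after seeing the data. They were estimated per library by loess (span 0.3, 2 passes) on the longest GENCODE M21 transcript of each symbol, which covered 98.1% of the genes tested with hymeglusin and 97.8% of those tested with age. Positions are RefSeq gene bounds on GRCm38.p6, the assembly of mm10, which held 99.2% of the symbols.

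The pipeline was tested on simulated data with the real means and library sizes. Each fold was given to 50 genes, and a further list of genes was raised 1.5-fold, with no transcript length trend. Far fewer genes were changed than were called in the real data (48.3% with hymeglusin and 28.6% with age), so the shares recovered may differ there. In the simulated hymeglusin comparison of 12873 genes, 62% of genes changed 1.25-fold, 90% changed 1.5-fold, 92% changed 2-fold and 100% changed 4-fold were recovered, with 15 false calls among 211. These 211 calls include members of the further raised list, which count neither in the shares nor as false. In the simulated age comparison of 16381 genes, the shares were 0%, 2%, 4% and 64%, with 7 false calls among 42.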

Results

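The series title links impaired ketone body production in Leydig cells with ageing of the testis. RNA sequencing counts were analysed from MLTC-1 mouse Leydig tumour cells given DMSO or hymeglusin (n = 3 each) and from primary Leydig cells of mice aged 2 or 24 months (n = 2 each). Total counts were 24370094, 34787330 and 25559451 in the DMSO libraries and 27490870, 28880182 and 33951121 with hymeglusin. They were 23668785 and 24234367 at 2 months and 17407456 and 23714601 at 24 months. The 10 most abundant genes took 2.77% to 4.80% of the counts in 8 libraries and 9.65% and 6.64% in the 24-month libraries. The labels do not say whether replicates were separate cultures or animals, so p-values measure the spread between these samples, which may be technical.

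The first comparison asked how hymeglusin, an inhibitor of the cytosolic HMG-CoA synthase Hmgcs1, changed gene expression in MLTC-1 cells. With hymeglusin, genes of ketone body, cholesterol and fatty acid synthesis, of fatty acid oxidation and of glycolysis fell, and cell cycle genes rose. Cyp17a1, a steroid-synthesis enzyme needed for androgens, fell from 887 ± 40.2 to 404 ± 23.9 CPM (mean ± SD, n = 3 each), a log2 fold change of -1.13 (SE 0.049, adjusted p = 1.13e-19). In all, 3069 of 12873 tested genes rose and 3149 fell, of which 368 and 148 changed at least 2-fold. Of 31 lists tested, 5 were called higher and 9 lower, and 6 of these calls held with an estimated correlation: ketone body synthesis and use, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation, glycolysis and cell cycle.

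Of the 9 tested genes of ketone body synthesis and use, 6 fell, and 7 fell when adjusted over the list alone (list median log2 -0.38, list adjusted p = 6.09e-08, adjusted p = 0.0407 with an estimated correlation). They included Acat1, which makes acetoacetyl-CoA (log2 -0.59, SE 0.047), Bdh1, which interconverts acetoacetate and beta-hydroxybutyrate (-0.38, SE 0.069), Aacs (-0.30, SE 0.056), and the monocarboxylate carriers Slc16a1 (-0.52, SE 0.050) and Slc16a3 (-1.53, SE 0.073). Oxct1, which starts the use of ketone bodies, stood at -0.10 (adjusted p = 0.0609, 0.00406 to 1 over the alternatives) and passed the threshold by DESeq2 (adjusted p = 0.0281), with the length offset (0.0209), with length and GC content (0.00406) and without hymeglusin replicate 2 (0.0475). Slc16a6 stood at 0.01 (adjusted p = 0.938).

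Of 25 tested genes of cholesterol synthesis, 24 fell and 1 rose, Lbr (log2 0.48, SE 0.050), with equal counts when adjusted over the list alone. The list median was -0.51 (list adjusted p = 1.32e-17, adjusted p = 0.0153 with an estimated correlation). Hsd17b7 fell by 0.84 (SE 0.048) and Mvd by 0.85 (SE 0.054) on the log2 scale. Hmgcs1 (chromosome 13, 119690351 to 119708260), the cytosolic HMG-CoA synthase, fell from 737 ± 19.4 to 538 ± 19.8 CPM (log2 -0.45, SE 0.046, adjusted p = 2.17e-10). In fatty acid synthesis, 14 of 17 genes fell, also when adjusted over the list alone (list adjusted p = 5.32e-13, adjusted p = 0.0351 with an estimated correlation), among them the desaturase Scd1 (log2 -0.89, SE 0.047) and the elongase Elovl6 (-0.86, SE 0.047). LXR targets went both ways, with 3 of 6 up and 2 down (list adjusted p = 0.883). The cholesterol exporter Abca1 rose (0.29, SE 0.047) and Lpcat3 fell (-0.50, SE 0.046).

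Of 23 genes of fatty acid oxidation, 19 fell and 1 rose, and 20 fell when adjusted over the list alone (list adjusted p = 1.33e-11, adjusted p = 0.0153 with an estimated correlation). Echs1 fell by 0.69 (SE 0.047) and Hadh by 0.63 (SE 0.045) on the log2 scale. Cpt1a, which brings fatty acids into mitochondria, rose by 0.13 (SE 0.048, adjusted p = 0.0252), but its adjusted p was 0.0889 without DMSO replicate 1, 0.0636 without DMSO replicate 2 and 0.0839 without hymeglusin replicate 3 (7.19e-05 to 0.419 over the alternatives). The glycolysis list also holds targets of the hypoxia response, and 18 of its 20 tested genes fell, with equal counts when adjusted over the list alone (list median log2 -0.74, list adjusted p = 1.67e-36, adjusted p = 0.0468 with an estimated correlation). Pgk1, a glycolytic kinase, fell from 1234 ± 35.2 to 588 ± 14.4 CPM (log2 -1.07, SE 0.045). Pdk1, which restrains pyruvate entry into the citrate cycle, fell by 1.56 (SE 0.049) and Bnip3, a mitophagy receptor, by 1.55 (SE 0.057). Car9 (log2 0.48, adjusted p = 0.0161) and Pfkfb3 (0.21, adjusted p = 0.0234) rose. Car9 was at an adjusted p of 0.126 without DMSO replicate 2 and 0.129 without hymeglusin replicate 3, and Pfkfb3 at 0.108 without DMSO replicate 3 and 0.112 without hymeglusin replicate 3. Over the alternatives it ran 0.00304 to 0.359 for Car9 and 0.000755 to 0.231 for Pfkfb3. Culture density and oxygen of the dishes are not given in the sources used here. Nuclear genes of oxidative phosphorylation fell in 29 of 44 cases, or 31 when adjusted over the list alone (list adjusted p = 1.02e-05, adjusted p = 0.391 with an estimated correlation), Sdhb by 0.62 (SE 0.046), and 1 gene, Ndufa1, rose (0.31).

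Among 19 genes of steroid hormone synthesis, 10 fell and 4 rose, or 10 and 5 when adjusted over the list alone (list adjusted p = 0.00275, adjusted p = 0.0917 with an estimated correlation). Besides Cyp17a1 (chromosome 19, 46667165 to 46673000), Cyp11a1, the side-chain cleavage enzyme, fell from 3509 ± 108 to 2413 ± 28.4 CPM (log2 -0.54, SE 0.043), Hsd3b1 by 0.59 (SE 0.045) and the lipoprotein receptor Scarb1 by 0.69 (SE 0.045), while Por rose (0.22, SE 0.050). Star, the mitochondrial cholesterol carrier, stood at 468 ± 8.02 and 502 ± 7.47 CPM (log2 0.10, SE 0.045, adjusted p = 0.0602, 0.000167 to 0.386 over the alternatives) and passed the threshold under total counts, upper quartile scaling, DESeq2, limma-voom, the stricter count filter and the offset for length and GC content. Leydig cell identity genes fell in 12 of 18 cases and 1 rose, also when adjusted over the list alone (list adjusted p = 1.45e-05, adjusted p = 0.107 with an estimated correlation). Lhcgr, the receptor of luteinising hormone, fell from 562 ± 16.8 to 309 ± 6.98 CPM (log2 -0.87, SE 0.046, adjusted p = 2.21e-17), and Inhba fell by 0.67 (SE 0.052). Insl3, a Leydig cell hormone, stood at -0.20 (SE 0.133, adjusted p = 0.25, 0.00672 to 0.925 over the alternatives) and was called with no count filter (0.00927). In the list of responses to luteinising hormone and cAMP, 5 of 10 genes rose and 1 fell, or 7 and 1 when adjusted over the list alone (list adjusted p = 0.0128, adjusted p = 0.107 with an estimated correlation), with the nuclear receptor Nr4a1 up by 1.15 (SE 0.060).

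Cell cycle genes rose in 25 of 36 cases, also when adjusted over the list alone (list median log2 0.37, list adjusted p = 5.35e-13, adjusted p = 0.0153 with an estimated correlation). The topoisomerase Top2a rose from 354 ± 8.37 to 607 ± 22.7 CPM (0.78, SE 0.046) and the mitotic cyclin Ccnb1 by 0.75 (SE 0.049). Mcm6 (-0.11) and Rrm2 (-0.12) fell, but lost their calls without DMSO replicate 2 (adjusted p = 0.182 and 0.101), hymeglusin replicate 1 (0.0699 and 0.203) or hymeglusin replicate 3 (0.0969 and 0.14). Mcm6 also lost it without DMSO replicate 3 (0.0819) or hymeglusin replicate 2 (0.0607), and Rrm2 without DMSO replicate 1 (0.158), and both lost it with total counts, upper quartile scaling and the stricter count filter. Over the alternatives the adjusted p ran 0.000594 to 1 for Mcm6 and 0.0116 to 0.982 for Rrm2. Immediate early genes rose in 14 of 20 cases and fell in 2, also when adjusted over the list alone (list adjusted p = 1.02e-05, adjusted p = 0.0701 with an estimated correlation), with Klf6 up by 0.83 (SE 0.070). Interferon response genes rose in 14 of 18 and fell in 1, or 15 and 1 when adjusted over the list alone (list adjusted p = 3.95e-06, adjusted p = 0.107 with an estimated correlation), with the immunoproteasome subunit Psmb8 up from 5.70 ± 0.591 to 16.3 ± 1.47 CPM. NRF2 antioxidant genes fell in 19 of 30 and 1 rose, also when adjusted over the list alone (list adjusted p = 6.8e-05, adjusted p = 0.107 with an estimated correlation), with Gsta4 down by a log2 of -0.64 (SE 0.045). Peritubular myoid and smooth muscle markers rose in 5 of 8 and fell in 1, also when adjusted over the list alone (list adjusted p = 0.0107, adjusted p = 0.107 with an estimated correlation), with Notch3 up by 1.36 (SE 0.088).

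Other lists on ageing and stress were not called, though members changed. Senescence and secreted factors held 10 higher and 3 lower genes of 19 (10 and 4 adjusted over the list alone, list adjusted p = 0.485), with the growth factor Vegfa at a log2 of -0.86 (SE 0.048). Cdkn1a, a cell cycle inhibitor, rose by 0.32 (SE 0.086, adjusted p = 0.00191). Cdkn2a stood at -0.13 (SE 0.049, adjusted p = 0.0311, 0.0115 to 1 over the alternatives) and was at 0.0743 without DMSO replicate 1, 0.0537 without DMSO replicate 3 and 0.194 without hymeglusin replicate 2, and lost its call with total counts (0.73), upper quartile scaling (0.104), the stricter count filter (0.0733) and the length offset (0.185). Foxo3 was at -0.05 (adjusted p = 0.441). Higher and lower genes numbered 7 and 4 of 17 for p53 targets (7 and 5 adjusted over the list alone), 8 and 8 of 23 for FOXO factors and targets, and 7 and 4 of 24 for histone deacetylases and acetyltransferases. They numbered 5 and 11 of 27 for the integrated stress response, 2 and 9 of 23 for endoplasmic reticulum chaperones, 2 and 5 of 13 for heat shock, 5 and 10 of 28 for lysosome and autophagy, and 5 and 4 of 11 for extracellular matrix. Of 8 antigen presentation genes 5 rose (list adjusted p = 0.073, 0.0254 with no count filter and 0.0461 without DMSO replicate 1, 0.000885 to 0.21 over the alternatives), among them B2m (0.35, SE 0.053). With no count filter the integrated stress response (0.0253, 0.00443 to 0.418 over the alternatives) and endoplasmic reticulum chaperones (0.0419, 0.00459 to 0.392) were called lower. The list adjusted p of the others ran from 0.149 for the integrated stress response to 0.883 for extracellular matrix, and counts adjusted over the list alone were equal where none is given. Median and mean went apart for extracellular matrix (-0.04 and 0.20), and the test of FOXO factors and targets pointed down against a median of 0.02.

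Markers of other cell types changed in small numbers. Macrophage (1 of 4) and spermatid (3 of 5) markers included rises, and lymphocyte (1 of 3) and Sertoli cell (4 of 8) markers included falls. Both directions were seen for spermatogonia and spermatocytes (3 higher and 1 lower of 7) and endothelium (2 and 1 of 6). None of these lists was called (list adjusted p from 0.241 to 0.846), with equal counts when adjusted over the list alone. The median of the spermatogonia and spermatocyte list was 0.13 and its mean -0.01. The receptor gene Kit, in the spermatogonia list, fell from 597 ± 7.39 to 328 ± 8.72 CPM. The 2 tested fibroblast markers and 1 red blood cell marker were too few for a list test, and of the former Pdgfra rose by 0.68 (adjusted p = 0.00953, 0.069 without hymeglusin replicate 3, 0.00264 to 0.16 over the alternatives).

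The largest rises named by the rule were those of the scaffold protein Ahnak, from 23.2 ± 0.107 to 84.3 ± 0.764 CPM (log2 1.86, SE 0.061), Wnt4 (1.80), Lmcd1 (1.76) and Arid5a (1.75). The largest falls were those of the mucin Muc2 (-2.45, SE 0.424, and -3.11 without hymeglusin replicate 3), Ankrd37 (-2.11), the mitochondrial adenylate kinase Ak4, from 239 ± 7.84 to 64.3 ± 3.49 CPM (-1.89, SE 0.053), and Zbtb32 (-1.79). With total counts in place of TMM, the median of all genes moved to a log2 of 0.11 and calls were 4659 higher and 1996 lower, 70.0% higher against 49.4%. In 1 fit of all 10 libraries, 645 genes were higher and 289 lower. That fit takes 1 spread per gene for MLTC-1 and primary cells. In the separate fits the biological coefficient of variation, the spread beyond counting error, was 0.0509 in MLTC-1 cells and 0.307 in primary cells over all genes. Calls lost with hymeglusin or gained with age in that fit thus rest on a spread that neither cell type had alone. Cyp17a1 (adjusted p = 0.00269) passed in that fit, and Hmgcs1 (0.349), Cyp11a1 (0.0977) and Bdh1 (0.16) did not, each the highest adjusted p among that gene's alternatives. Of 143 genes followed over the alternatives, 74 lost their call in it.

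**Figure D1:**
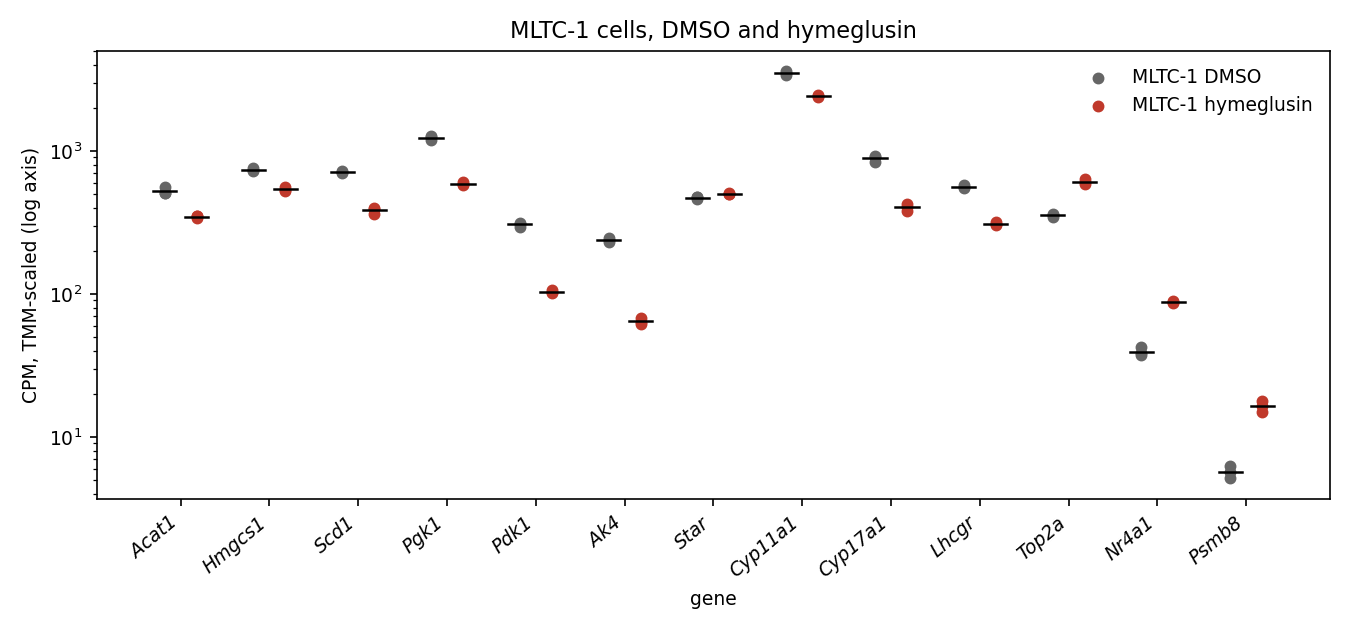
TMM-scaled CPM (log axis) of 13 genes in MLTC-1 cells; each point is 1 library (n = 3 per group) and each black line is the group mean. Cyp17a1 lies at 887 CPM in DMSO and 404 CPM with hymeglusin, while Star lies at 468 and 502 CPM.

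The second comparison asked how Leydig cells of old mice differed from those of young mice. At 24 months, genes of secreted senescence factors, interferon response, antigen presentation and immediate early response rose more often than they fell, and extracellular matrix genes fell more often. With the length offset, 6 extracellular matrix genes fell and 2 rose, and that list was not called (camera adjusted p = 0.204). Of markers of other cells, 17 of 23 for spermatids and 8 of 18 for macrophages rose, or 5 and 3 with the length offset (both lists at an adjusted p = 0.655 with an estimated correlation). Summed macrophage markers were 53 and 67.1 CPM at 2 months and 209 and 162 CPM at 24 months. Whether the immune genes rose in Leydig cells or came from other cells of the preparation was not tested. Cdkn1a (chromosome 17, 29090979 to 29100722), a cell cycle inhibitor, rose from 19.4 ± 1.18 to 127 ± 7.75 CPM (mean ± SD, n = 2 each), a log2 fold change of 2.71 (SE 0.333, adjusted p = 0.0027). Of 16381 tested genes, 2214 rose and 2471 fell. The calls followed transcript length, with 814 of 1603 genes higher and 25 lower in the decile of shortest transcripts and 17 higher and 876 lower in the longest. Of 32 lists tested by camera, 13 were called higher and 1 lower, and 0 with an estimated correlation, where 2 lists were at an unadjusted p under 0.05. By fry, 3 lists were called, each at an adjusted p = 0.0427. Senescence and secreted factors and interferon response were higher, and histone deacetylases and acetyltransferases were lower. Leaving out 1 primary cell library leaves 1 in its age group, so the spread then comes from the other pair alone. The 2-month pair lay closer than the 24-month pair (chi-square per degree of freedom 18.9 and 134). Calls gained without a 24-month library or lost without a 2-month library therefore say little about single genes or lists. Where such values are given below, they cannot be told apart from this change of spread.

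For ketone body synthesis and use, 1 of 11 genes rose (list adjusted p = 0.841), and with the length offset 2 rose and 1 fell. With edgeR 0 passed when adjusted over the list alone, 3 were at an unadjusted p under 0.05, DESeq2 called 2 higher and 1 lower, and limma-voom called 1 and 1. Summed over the list, levels were 5333 and 4860 CPM at 2 months and 3370 and 3761 CPM at 24 months, though the list median was 0.13. The sum is set mostly by abundant members and was not tested. Bdh1 (chromosome 16, 31422297 to 31458901) rose from 16.7 ± 1.11 to 37.4 ± 5.25 CPM (log2 1.17, SE 0.326, adjusted p = 0.0285). Its adjusted p was 0.091 with total counts (0.000139 to 0.331 over the alternatives). Not called were Acat1 (log2 0.22, adjusted p = 0.623), Oxct1 (-0.67, adjusted p = 0.135), Slc16a3 (-1.29, adjusted p = 0.0632) and Hmgcs1 (-0.62, adjusted p = 0.249). Slc16a3 passed by DESeq2 (0.0287), by limma-voom (0.0299) and with no count filter (0.00385), and in the fit of all 10 libraries Oxct1 (0.00169) and Slc16a3 (0.0178) passed. Oxct1 and Slc16a3 also passed without either 24-month library, and Hmgcs1 without 24-month replicate 2, but there the spread comes from the 2-month pair alone. Over the alternatives the adjusted p ran 0.00169 to 0.642 for Oxct1, 6.36e-05 to 0.385 for Slc16a3 and 0.000284 to 0.681 for Hmgcs1.

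Of 20 genes of steroid hormone synthesis, 3 rose and 4 fell, also when adjusted over the list alone (list adjusted p = 0.749), and 1 and 3 did so with the length offset. Cyp21a1 (chromosome 17, 34801348 to 34804426), the 21-hydroxylase of adrenal steroid synthesis, rose from 6.34 ± 1.57 to 549 ± 205 CPM (log2 6.44, SE 0.479, adjusted p = 0.000485). Srd5a1, a steroid 5-alpha-reductase, fell from 116 ± 10.5 to 11.2 ± 1.04 CPM (-3.38, SE 0.346, adjusted p = 0.0014). The main enzymes of testosterone synthesis were not called. Star was at a log2 of -0.56 (SE 0.342, adjusted p = 0.235, 0.0096 to 0.956 over the alternatives), Cyp11a1 at -0.23 (SE 0.361, adjusted p = 0.657), Cyp17a1 at -0.25 (SE 0.348, adjusted p = 0.612), Hsd3b1 at 0.71 (SE 0.34, adjusted p = 0.139) and Hsd17b3 at 0.00 (SE 0.33, adjusted p = 0.992). Without 24-month replicate 1, Cyp11a1 (0.0247) and Hsd3b1 (0.0438) passed, and without 24-month replicate 2, Star (0.0245) and Hsd3b1 (0.00374). Star (0.0096) and Hsd3b1 (0.00105) also passed in the fit of all 10 libraries. Hsd17b3 turned to -0.88 (adjusted p = 0.0322) with offsets for length and GC content. Over the alternatives the adjusted p ran 0.0247 to 0.977 for Cyp11a1, 0.00105 to 0.789 for Hsd3b1 and 0.0322 to 0.987 for Hsd17b3.

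Leydig cell identity genes went both ways, with 5 higher and 4 lower of 19, or 6 and 6 when adjusted over the list alone (list adjusted p = 0.749). The length offset left 4 and 1. The list median was -0.30, against a mean of 0.19 and a test pointing up. The transcription factor Gata6 rose from 1.59 ± 0.00926 to 64.6 ± 12.9 CPM (5.34, SE 0.397, adjusted p = 0.000485) and the orphan receptor Nr0b1 rose by 2.46 (SE 0.401). Lhcgr fell (-1.49, SE 0.342, adjusted p = 0.0163) and Insl3, which lies within the bounds of Jak3, rose (1.73, SE 0.483, adjusted p = 0.0285), the latter by 0.75 without 24-month replicate 1. With the transcript length offset, Lhcgr was at -0.24 (adjusted p = 0.626) and Insl3 at 0.05 (adjusted p = 0.941), and Insl3 was at an adjusted p of 0.0662 with total counts. Without 2-month replicates 1 and 2, the adjusted p of Lhcgr was 0.236 and 0.101 and that of Insl3 was 0.212 and 0.217 (over the alternatives 7.01e-05 to 0.774 and 1.13e-05 to 0.941). Among genes of the response to luteinising hormone and cAMP, 4 of 15 rose and 4 fell, or 4 and 5 when adjusted over the list alone (list adjusted p = 0.749). Of these, 6 rose and 2 fell with the length offset, and the list median of 0.17 went to 0.47.

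Senescence and secreted factors rose in 13 of 29 cases and fell in 2, or 15 and 2 when adjusted over the list alone (list median log2 1.52, list adjusted p = 1.44e-05, adjusted p = 0.571 with an estimated correlation). With the length offset 10 rose and 2 fell, at a list median of 0.66 (list adjusted p = 0.00257, 1.11e-06 to 0.571 over the alternatives). The chemokine Ccl2 rose from 0.744 ± 0.30 to 35.8 ± 12.4 CPM (5.57, SE 0.497) and Cxcl10 by 4.52 (SE 0.474, and 3.82 without 24-month replicate 2), while Vegfa fell (-2.58, SE 0.355). Cdkn2a was at 2.11 (SE 0.946, adjusted p = 0.117), and at 0.0114 in the fit of all 10 libraries (0.0114 to 0.684 over the alternatives). Interferon response genes rose in 13 of 27 and fell in 1, or 17 and 3 when adjusted over the list alone (list adjusted p = 0.000103, adjusted p = 0.571 with an estimated correlation), with the guanylate-binding protein Gbp2 up by 2.96 (SE 0.425). Antigen presentation genes rose in 9 of 14 and fell in 1, or 10 and 1 when adjusted over the list alone (list adjusted p = 0.000108, adjusted p = 0.571 with an estimated correlation), and 5 higher with the length offset, with the class II invariant chain Cd74 up from 0.798 ± 0.0871 to 12.6 ± 3.38 CPM (3.97, SE 0.476). Immediate early genes, which also respond to cell dissociation, rose in 11 of 20, or 14 when adjusted over the list alone (list adjusted p = 2.63e-07, adjusted p = 0.655 with an estimated correlation), with Ier3 up from 48.2 ± 4.01 to 493 ± 8.04 CPM (3.36, SE 0.344) and Atf3 by 3.26 (SE 0.364). p53 targets rose in 8 of 24, or 9 when adjusted over the list alone (list adjusted p = 0.0287, adjusted p = 0.722 with an estimated correlation), with Plk2 up by 2.87 (SE 0.438). The p53 list was at 0.114 without 2-month replicate 1, 0.0588 without 2-month replicate 2 and 0.469 without 24-month replicate 2 (0.00067 to 0.722 over the alternatives). Fitted with the length offset, 10 interferon response genes, 13 immediate early genes and 6 p53 targets were higher.

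Extracellular matrix genes fell in 11 of 26 cases and rose in 2, or 12 and 2 when adjusted over the list alone, and 6 fell with the length offset (list median log2 -0.79, list adjusted p = 0.000646, adjusted p = 0.571 with an estimated correlation, 0.204 with the length offset). The collagen gene Col1a2 fell from 232 ± 27.1 to 11.1 ± 1.16 CPM (-4.38, SE 0.366, adjusted p = 0.000593) and the fibrillin gene Fbn1 from 33.8 ± 0.0772 to 1.35 ± 0.204 CPM (-4.65, SE 0.40). Nuclear genes of oxidative phosphorylation rose in 23 of 44, or 29 when adjusted over the list alone (list adjusted p = 2.63e-07, adjusted p = 0.722 with an estimated correlation), but 4 rose with the length offset (list adjusted p = 0.34). NRF2 antioxidant genes rose in 12 of 30 and fell in 3, or 13 and 4 when adjusted over the list alone and 5 and 2 with the length offset (list adjusted p = 0.00877, adjusted p = 0.722 with an estimated correlation, 0.204 with the length offset and 0.104 without 2-month replicate 2), with the glutathione transferase Gsta2 up by 3.79 (SE 0.424). LXR targets rose in 5 of 10, or 6 with 1 lower when adjusted over the list alone and 4 with the length offset (list adjusted p = 0.021, adjusted p = 0.571 with an estimated correlation, 0.0617 with the length offset). The LXR list was at 0.0928 without 2-month replicate 2 and 0.0515 without 24-month replicate 2, and the apolipoprotein Apoc1 rose by 2.92 (SE 0.411). Over the alternatives the list adjusted p ran 3.08e-06 to 0.923 for extracellular matrix, 4.27e-13 to 0.923 for oxidative phosphorylation, 0.000381 to 0.923 for NRF2 and 0.0121 to 0.571 for LXR targets.

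Lists not called with age held, as higher and lower genes, 6 and 4 of 26 for cholesterol synthesis, 2 and 6 of 17 for fatty acid synthesis, 1 and 2 of 23 for fatty acid oxidation, 4 and 4 of 25 for FOXO factors and targets, and 1 and 5 of 26 for histone deacetylases and acetyltransferases. They held 5 and 3 of 28 for the integrated stress response, 1 and 4 of 23 for endoplasmic reticulum chaperones, 1 and 4 of 36 for the cell cycle, and 2 and 2 of 28 for lysosome and autophagy. In glycolysis 1 of 20 genes rose, and in heat shock 2 of 14. These numbers changed with the length offset. They were then 8 and 2 for FOXO factors and targets, 3 and 1 for deacetylases and acetyltransferases, 2 and 2 for fatty acid synthesis and 4 and 1 for cholesterol synthesis. They were 4 and 5 for the integrated stress response, 1 and 3 for the cell cycle, 4 and 1 for heat shock and 3 and 1 for lysosome and autophagy. In glycolysis 4 then rose, and 2 endoplasmic reticulum chaperones fell. Fatty acid oxidation stayed at 1 and 2. Adjusted over the list alone and without the offset, 7 fell in fatty acid synthesis, 4 among the deacetylases and acetyltransferases, and 2 with no rise in fatty acid oxidation. In glycolysis 0 then passed with edgeR, where 5 genes were at an unadjusted p under 0.05 and DESeq2 called 4 and limma-voom 2. List adjusted p-values ran from 0.12 for fatty acid synthesis to 0.749 for cholesterol synthesis, and fatty acid synthesis passed without 24-month replicate 1 (0.037, 0.037 to 0.923 over the alternatives). The list of deacetylases and acetyltransferases, not called by camera, was called lower by fry (adjusted p = 0.0427, 0.0427 to 0.966 over the alternatives). The cyclin Ccnd2 fell by 3.32 (SE 0.365) and the arginine carrier Slc7a1 by 3.28 (SE 0.393) on the log2 scale, and the transcription factor Cebpb rose by 2.53 (SE 0.332).

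Markers of other cells differed between the ages. Summed spermatid markers were 3147 and 4399 CPM in the 2-month libraries and 14310 and 8446 CPM in the 24-month libraries. Of these, 17 of 23 rose, or 19 when adjusted over the list alone (list adjusted p = 3.17e-08, adjusted p = 0.655 with an estimated correlation), and 5 rose with the length offset. Tnp1, a spermatid nuclear protein, rose by 2.01 (SE 0.372, adjusted p = 0.00985), but was at an adjusted p of 0.439 with the length offset (2.52e-06 to 0.439 over the alternatives). Macrophage markers summed to 53 and 67.1 against 209 and 162 CPM, with 8 of 18 higher, also when adjusted over the list alone (list adjusted p = 0.00027, adjusted p = 0.655 with an estimated correlation), among them the lysozyme gene Lyz2 (2.79, SE 0.399). With the length offset 3 macrophage markers rose, and the list median of 1.67 went to 0.99 (list adjusted p = 0.0254, 9.53e-05 to 0.655 over the alternatives). Lymphocyte markers summed to 7.17 and 5.71 against 28.2 and 38.0 CPM, with 1 of 5 higher, or 4 when adjusted over the list alone and 1 with the length offset (list adjusted p = 0.0124, adjusted p = 0.571 with an estimated correlation, 0.0515 without 24-month replicate 2). The called gene, Jchain, rose by 5.24 (SE 0.687), by 5.95 without 2-month replicate 2 and by 4.16 without 24-month replicate 2. Endothelial markers summed to 39.5 and 41.8 against 102 and 55.0 CPM, with 3 of 11 higher, also when adjusted over the list alone, and 6 with the length offset (list adjusted p = 0.0287, adjusted p = 0.722 with an estimated correlation, 0.261 without 24-month replicate 1). Over the alternatives the list adjusted p ran 0.000856 to 0.571 for lymphocyte and 0.00186 to 0.722 for endothelial markers.

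Fibroblast markers were 591 and 620 against 382 and 454 CPM in sum, yet 6 of 15 rose and 2 fell, or 7 and 2 when adjusted over the list alone and 5 and 2 with the length offset. Ly6a rose by 4.72 (SE 0.470, and 5.31 without 2-month replicate 2) and Pdgfra fell by 2.18 (SE 0.407, and by 2.86 without 24-month replicate 2). The fibroblast list was called upward (list adjusted p = 0.0459, adjusted p = 0.655 with an estimated correlation), but not without 2-month replicate 1 (0.101), 2-month replicate 2 (0.063), 24-month replicate 1 (0.261) or 24-month replicate 2 (0.324), with 0.00908 to 0.655 over the alternatives. Not called were Sertoli cell markers (2 higher and 2 lower of 16, or 3 and 2 with the length offset, list adjusted p = 0.112 without it) and peritubular myoid and smooth muscle markers (3 and 1 of 12, or 4 and 1 adjusted over the list alone, list adjusted p = 0.12, and 0.0189 with the length offset, where 2 were higher, 0.0189 to 0.722 over the alternatives). Of 19 spermatogonia and spermatocyte markers 2 were higher and 1 lower (list adjusted p = 0.636), and neither the higher nor the lower ones passed with the length offset. Adjusted over the list alone, 0 of these passed with edgeR, where 6 were at an unadjusted p under 0.05 and DESeq2 called 6 and limma-voom 4. Of 2 red blood cell markers 0 were called by edgeR or DESeq2 and 1 by limma-voom, and 1 was at an unadjusted p under 0.05.

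The largest rises named by the rule included genes at 0 counts in both 2-month libraries. Kng2, a kininogen (chromosome 16, 22985852 to 23029101), was at least 958-fold higher, and S100a9, Ngp and S100a8, which are abundant in neutrophils, were at least 356-fold, 279-fold and 232-fold higher. S100a9 stood at 4.34 and 30.7 CPM in the 24-month libraries, and the adjusted p of S100a9, Ngp and S100a8 with the length offset was 0.196, 0.126 and 0.28 (over the alternatives 2.29e-35 to 0.284, 3.3e-31 to 0.258 and 6.4e-28 to 0.377). The fitted log2 fold changes of S100a9, Ngp and S100a8, 11.64, 11.29 and 10.98, went to 12.57, 12.22 and 12.02 without 24-month replicate 1 and 9.54, 9.16 and 7.45 without replicate 2. Obp2a was 628-fold higher (95% interval 173 to 5200), Obp2b 192-fold (52.7 to 1590) and Serpina3m 216-fold (59.3 to 1790). Their fitted log2 fold changes were 8.22, 10.46 and 10.52 without 2-month replicate 1, 11.96, 6.5 and 6.55 without 2-month replicate 2, and 6.90 for Obp2b without 24-month replicate 1. The liver-type secreted protein Fetub rose by 7.10 (SE 0.486), and the acute-phase protein Saa3 by 7.08 (SE 0.609), with 7.84 without 2-month replicate 1 and 6.42 without 24-month replicate 1. The largest falls included those of Grm7, 121-fold higher at 2 months (41.1 to 589, fitted log2 -6.22 without 24-month replicate 1 and -10.7 without replicate 2), the collagen gene Col26a1 (-5.77, SE 0.459), Svep1 (-5.69, SE 0.414) and the water channel Aqp5 (-5.61, SE 0.445).

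The median of all genes moved to a log2 of -0.21 with total counts, where 531 genes were higher and 1301 lower (29.0% higher against 47.3%), and to 0.17 with upper quartile scaling, where 2626 were higher and 1781 lower (59.6% higher). With the transcript length offset, 1378 genes rose and 889 fell, of which 722 and 703 were also called without it. Calls were 239 higher and 602 lower without 2-month replicate 1, 481 and 972 without 2-month replicate 2, 2655 and 4016 without 24-month replicate 1, and 4259 and 5628 without 24-month replicate 2.

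**Figure D2:**
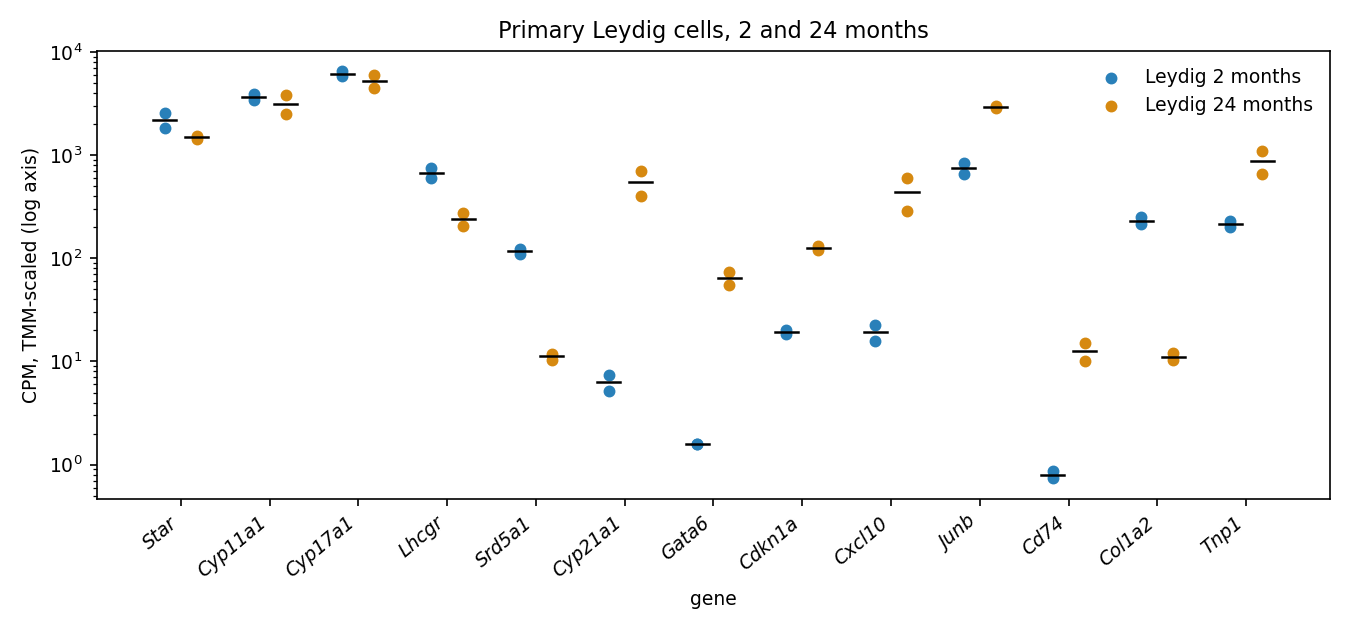
TMM-scaled CPM (log axis) of 13 genes in primary Leydig cells; each point is 1 library (n = 2 per age) and each black line is the group mean. Cdkn1a lies at 19.4 CPM at 2 months and 127 CPM at 24 months, and Srd5a1 lies at 116 and 11.2 CPM.

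**Figure D3:**
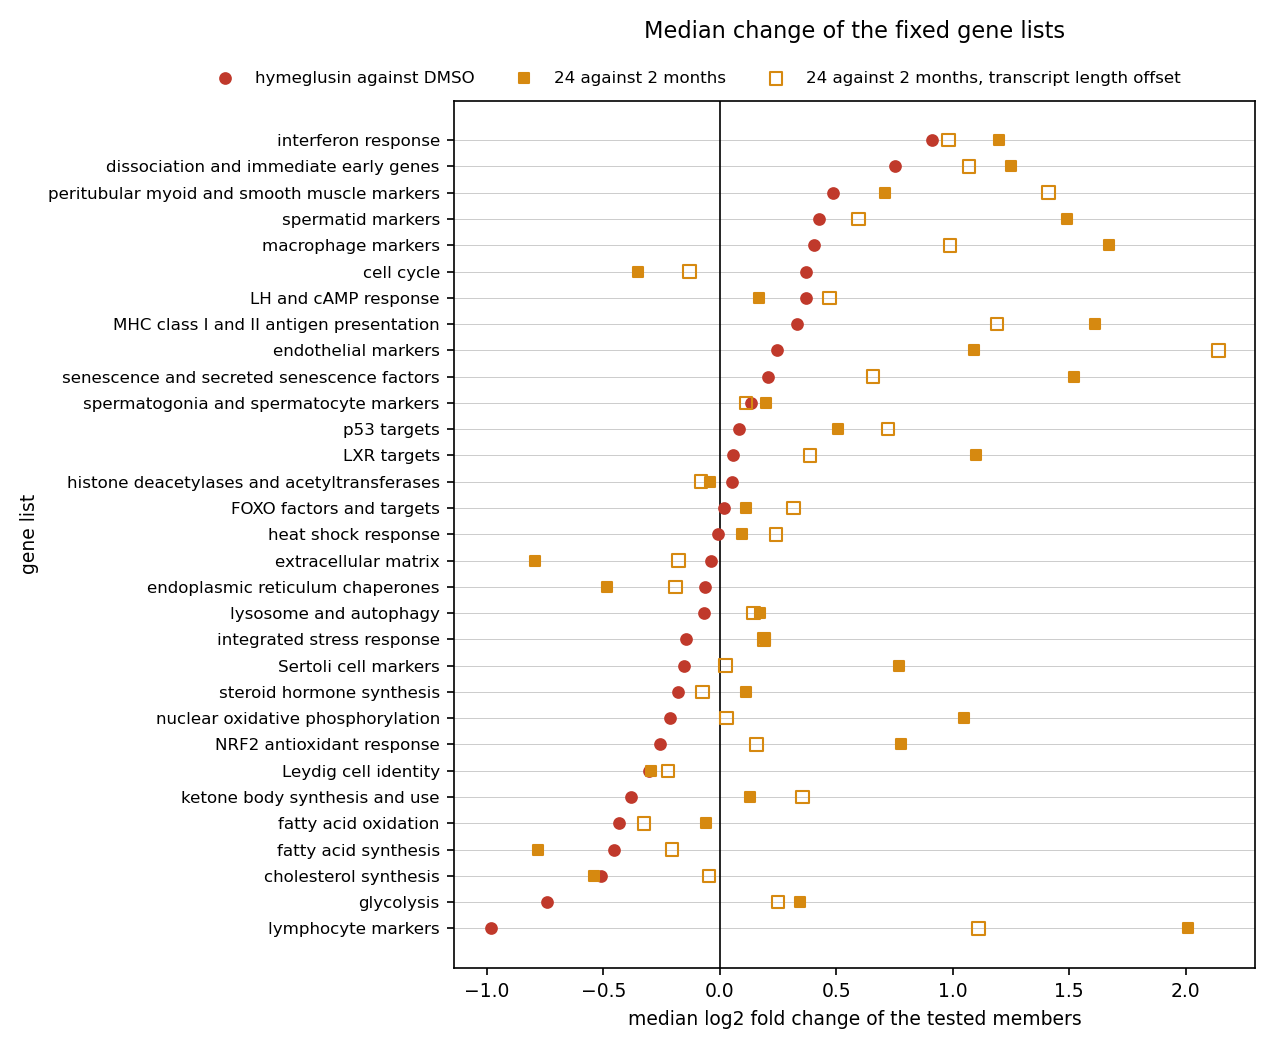
Median log2 fold change of the tested members of each list tested in both comparisons, with hymeglusin (circles), with age (filled squares) and with age after the transcript length offset (open squares). The glycolysis list lies at -0.74 with hymeglusin and 0.34 with age, and the spermatid list moves from 1.49 to 0.60 with the offset.

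**Figure D4:**
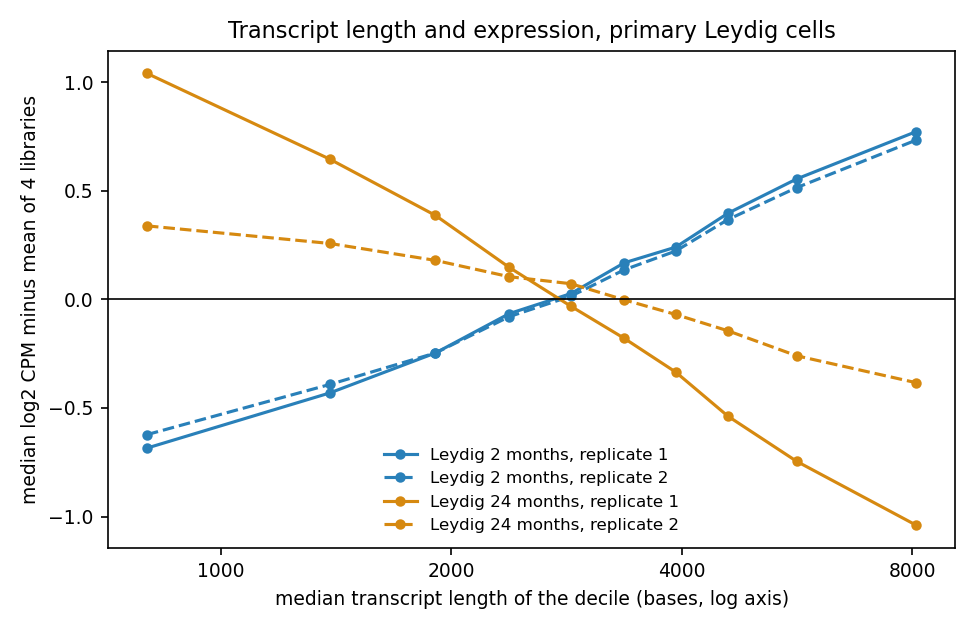
Median difference of log2 CPM from the mean of the 4 primary cell libraries, per decile of transcript length (bases, log axis), with a line for each library. The shortest minus the longest decile is -1.46 and -1.36 in the 2-month libraries and 2.08 and 0.72 in the 24-month libraries.

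The third comparison asked whether the inhibitor and age changed the same genes. Among 12356 genes tested in both, genes that rose with hymeglusin were more often lower and less often higher with age than independent lists would give. With the length offset no overlap was called by Fisher's exact test and both odds ratios turned, to 0.907 and 1.04, and both also turned with a minimum log2 fold change of 1, to 0.653 and 1.72. Rises with hymeglusin and falls with age shared 640 genes where 533.1 were expected (odds ratio 1.36, 95% interval 1.22 to 1.51, Fisher's exact test, adjusted p = 3.23e-08). Rises in both shared 260 where 311.8 were expected (odds ratio 0.772, adjusted p = 7e-04). Falls in both shared 566 where 551.3 were expected (odds ratio 1.04, adjusted p = 0.576), and falls with hymeglusin with rises with age shared 318 where 322.4 were expected (odds ratio 0.98, adjusted p = 0.786). The Spearman correlation of log2 fold changes across genes, which are not independent replicates, was -0.0345 (Pearson 0.00605). It turned to 0.0185 with the length offset in the age comparison only.

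Genes that rose in both included the regulators Arid5a (log2 1.75 with hymeglusin and 4.79 with age), Gadd45b (1.15 and 4.07), Irf1 (0.61 and 3.79) and Atf3 (1.24 and 3.26) and the small heat shock protein Cryab (0.77 and 3.35). Genes that fell in both included Aoc3 (-1.37 and -3.31), Chst2 (-0.91 and -3.35), Trib2 (-0.32 and -3.87) and Srd5a1 (-0.21 and -3.38, with hymeglusin at an adjusted p of 0.0802 with total counts, 3.25e-06 to 0.605 over the alternatives). Opposite directions were seen for Gata6 (-0.26 and 5.34), Ier3 (-0.52 and 3.36), Fbn1 (0.47 and -4.65) and Arhgef25 (0.32 and -3.57). The 200 top genes of each direction of age were not called as sets in the hymeglusin comparison (adjusted p = 0.45 and 0.887), nor those of hymeglusin in the age comparison (adjusted p = 0.11 for higher and 0.0739 for lower genes). Without the offset both hymeglusin sets pointed lower with age (median log2 -0.291 for higher and -0.315 for lower genes). The genes higher with hymeglusin thus went the other way with age. Their set passed without DMSO replicate 1 (camera adjusted p = 0.0469). The set of lower genes passed without DMSO replicate 1 (0.0104) and without hymeglusin replicate 2 (0.00892).

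With the transcript length offset, the lowest adjusted p of Fisher's exact test was 0.138, for falls in both, where 218 genes were shared and 193 expected (unadjusted p = 0.0345). The odds ratio of rises with hymeglusin and falls with age was 1.01 without 24-month replicate 2 and 1.13 without 2-month replicate 2. For rises in both it turned to 1.65 without 2-month replicate 1 and 1.35 without 2-month replicate 2, and was 0.883 without hymeglusin replicate 2 (Fisher's exact test, adjusted p = 0.0862). Falls with hymeglusin and rises with age were called at 0.82 without hymeglusin replicate 2, 0.564 without 2-month replicate 2 and 1.29 without 24-month replicate 1. Falls in both were called at 1.29 without DMSO replicate 1, 1.16 without hymeglusin replicate 2, and at an adjusted p of 3.6e-07 without 24-month replicate 2.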

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

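The tests with offsets for transcript length, or length and GC content, were chosen only after the result was seen. Of 2415 values of 143 genes with hymeglusin under the alternatives, 2268 kept their direction and side of the threshold, 115 lost a call, 14 gained one and 18 moved without a call. With age it was 1977 of 2241 for 151 genes, with 210 calls lost, 34 gained, 15 moved and 5 reversed. Of list values, 430 of 465 with hymeglusin and 336 of 416 with age kept direction and side. Depth and replicates may limit small changes. In simulated data 90% of genes changed 1.5-fold were recovered in the hymeglusin design of 12873 genes and 4% of genes changed 2-fold in the age design of 16381 genes. Far fewer genes were changed there than were called in the real data, so these shares do not give the power of the real tests.

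Genes called higher and lower with hymeglusin numbered 4659 and 1996 with total counts, 368 and 148 with a minimum log2 fold change of 1, which the alternative's construction lowers, and 645 and 289 in 1 fit of all libraries. With age they numbered 531 and 1301 with total counts, 4309 and 4559 in the fit of all libraries, 1378 and 889 with the length offset, and 1508 lower with length and GC content. Leaving out 1 library gave 239 to 4259 higher and 602 to 5628 lower with age, lowest without 2-month replicate 1 and highest without 24-month replicate 2. Those age fits leave 1 library in an arm, which is assumed to vary like the other group. The fit of all libraries takes 1 spread per gene for MLTC-1 and primary cells, whose spreads differed in the separate fits. Apart from the minimum fold change, the cause was not tested.

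Lists called higher and lower with hymeglusin numbered 1 and 5 with an estimated correlation, 1 and 5 with that and the length offset, and 10 and 16 by fry, which compares a list with no other genes. With age they numbered 0 and 0 by camera with an estimated correlation, where 2 lists were at an unadjusted p under 0.05, and 0 and 0 with that and the length offset, while fry called 2 higher. Lower lists numbered 0 with the length offset, 0 with length and GC content, and 1 to 2 with 1 library left out, the latter without 24-month replicate 1.

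The overlap of the calls also moved. For rises with hymeglusin and rises with age the odds ratio was 1.72 with the minimum fold change, 1.03 in the fit of all libraries, 1.04 with the length offset, 0.938 with length and GC content, and from 0.646 without 24-month replicate 1 to 1.65 without 2-month replicate 1. For rises with hymeglusin and falls with age it was 0.653 with the minimum fold change, 0.907 with the length offset, 0.951 with length and GC content, and from 1.01 without 24-month replicate 2 to 1.43 without DMSO replicate 3. For falls with hymeglusin and rises with age it was 1.52 (adjusted p = 0.0159) with total counts, 1.11 with upper quartile scaling, 1.1 by DESeq2, 1.04 by limma-voom, 1.15 with the stricter count filter, 1 with the minimum fold change, 1.05 with the replicate block, 1.01 with the length offset, 1.1 with length and GC content, and from 0.564 without 2-month replicate 2 to 1.29 without 24-month replicate 1. For falls in both it was 1.18 (adjusted p = 0.0461) with total counts, 0.976 with upper quartile scaling, 1.53 with no count filter, 0.805 with the stricter filter, 1.84 in the fit of all libraries, and from 0.962 without 2-month replicate 1 to 1.29 without DMSO replicate 1. The cause was not tested.

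The median log2 fold change of the 200 genes highest with age was 0.0035 in the hymeglusin comparison with the replicate block and -0.066 to 0.11 with 1 library left out. That of the 200 lowest was 0.020 with the block, -0.016 with the length offset, -0.071 with length and GC content, and -0.031 to 0.085 with 1 library left out. In the age comparison the 200 genes highest with hymeglusin were at -0.021 with the length offset and -0.50 to -0.23 with 1 library left out. The 200 lowest were at -0.17 with length and GC content and -0.55 to -0.25 with 1 library left out. Directions with age turned for Foxo1, at 0.32 with the length offset and 0.33 with length and GC content, and for Hdac4, at 0.040 with the length offset. They also turned with length and GC content for Hsd17b3, at -0.88, and Insl3, at -0.21. The cause was not tested.

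With the replicate number as a block, 3127 genes were higher and 3233 lower with hymeglusin, and 2088 and 2686 with age. Deviations of libraries with the same number correlated at 0.00239, -0.0245 and 0.0318 across genes in the MLTC-1 groups, where not every library correlated best with its own number, so the samples were taken to share only a number. With 2 libraries per age the primary cells give a single value, -0.0905, fixed in size for all pairs by centring, which cannot show whether the numbers pair the samples. With the block and hymeglusin, Star (adjusted p = 0.0413, 0.000167 to 0.386 over the alternatives), Insl3 (0.00672, 0.00672 to 0.925) and Oxct1 (0.0412, 0.00406 to 1) gained a call. With age Slc16a3 gained one (0.012, 6.36e-05 to 0.385) and the fibroblast list lost its own (0.0637, 0.00908 to 0.655). The block changed no other call of the named genes or lists.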

Other observations

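The offsets for length and GC content were chosen only after the result was seen, as were the tests of library quality, of spermatid transcripts, of targets of hypoxia-inducible factor and of differences between dishes.

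Beside Cyp21a1 and Gata6, further genes outside the rule, chosen after their values were seen, rose in the 24-month cells. Akr1b7, an aldo-keto reductase, rose from 3.4 ± 0.294 to 19.9 ± 3.02 CPM (mean ± SD, n = 2 each, log2 2.55, SE 0.382, edgeR adjusted p = 0.00565). The growth factor Igf2 rose from 60.8 ± 9.62 to 830 ± 23.1 CPM (log2 3.77, SE 0.361, edgeR adjusted p = 0.00113). Ly6d, a surface protein, rose by 7.07 (SE 0.549, and 6.28 without 24-month replicate 1). Sult1e1, an oestrogen sulfotransferase, rose by 2.47 (SE 0.349, adjusted p 5.38e-11 to 0.0602 over the alternatives). Agt, the angiotensin precursor, rose by 2.48 (SE 0.406, adjusted p 3.18e-09 to 0.105 over the alternatives). The secreted lipocalin Lcn2 rose by 1.91 (SE 0.444) and by 1.19 without 24-month replicate 1. It was at an adjusted p of 0.0644 with the length offset (5.64e-06 to 0.219 over the alternatives).

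The age comparison followed transcript length, with a median log2 fold change 2.82 higher in the decile of shortest transcripts than in the longest, against -0.0792 with hymeglusin. Thinning the 4 libraries at random to 17407456 counts left the difference at 2.84. Such thinning keeps each gene's expected share of its library, so the difference could hardly fall and this cannot decide on depth. The 24-month libraries differed from each other by 1.36 and the 2-month libraries by 0.1. RNA or library quality of single libraries may therefore contribute. Yet the trend was 2.13 without 24-month replicate 1 and 3.48 without 24-month replicate 2. Against the mean of the 4 libraries it was 2.08 and 0.722 at 24 months and -1.46 and -1.36 at 2 months. A single library thus does not account for all of it. RNA or library quality that differs between the ages and a difference in the cells with age stay open and were not tested.

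Spermatid markers had a median log2 fold change of 1.49 at 24 months, and of 10000 random lists matched on transcript length, 0.1% were as high (their median 0.743, middle 95% 0.239 to 1.24). The random genes were drawn singly while the spermatid members moved together, so that spread is too narrow for this list. The share therefore cannot decide whether length is the whole cause. With the length offset the list median was 0.596 and 22 of 23 members lay above 0, 5 of them called, so germ cell RNA carried over in the preparation may contribute. Members moved together (estimated correlation 0.55 without the offset), so their 95% interval of 0.39 to 0.784 is too narrow, and the list was at an adjusted p = 0.645 with the length offset and an estimated correlation (1.6e-09 to 0.655 over the alternatives). The abundant members Prm1 and Prm2, chosen after their values were seen, were at log2 2.23 and 2.19, and at 0.53 (adjusted p = 0.246, 5.59e-07 to 0.246 over the alternatives) and 0.60 (adjusted p = 0.207, 7.46e-07 to 0.207) with the length offset, where folds were smaller and neither was called. Without 24-month replicate 1 they were at 1.55 and 1.37, with adjusted p = 0.117 and 0.143 without 2-month replicate 1 and 0.0527 and 0.0629 without 2-month replicate 2, and a difference in the cells with age stays open.

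The glycolysis list, lower with hymeglusin, stood at a median log2 of -0.795 with offsets for length and GC content (camera adjusted p = 3.6e-42), which argues against such bias. Of 26 tested targets of hypoxia-inducible factor outside the list, 23 or 88.5% were lower and 1 was higher (median -0.852, camera p = 0.0047 with an estimated correlation). Leaving out those already named, 18 of 21 were lower (median -0.844, limma camera, unadjusted p 0.00533). A hypothesis is that activity of that factor may have been lower with the inhibitor. Car9 and Pfkfb3, which sit in the glycolysis list and so were not among these targets, rose, however. The SD of the mean log2 CPM of the list within groups was 0.0657 against a difference of 0.748 between groups, a ratio of 0.0878. Culture density or oxygen shared by the dishes of a group cannot be told apart from the inhibitor, since the labels give neither.

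Of the 10 splits of the 6 MLTC-1 libraries, 1 gave as many called genes as the real one, itself, with 6218 genes against a highest other of 0 by edgeR, where the other splits had 59 to 240 genes at an unadjusted p under 0.05. Every other split mixes the treatments in each group, which adds the treatment difference to the spread. The 0 genes called there therefore do not show what unrelated groups would give. For lists, 1 split gave as many, the real one with 14 against a highest other of 12. The other splits called 6 to 12 lists by camera at the preset correlation, though 0 genes were called. They keep part of the treatment difference, so this cannot show how many list calls at that setting are false. The 10 splits are too few for a share under 0.05.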
